A study of Saccharomyces cerevisiae with 11 samples.

How the data were processed

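RNA abundance was compared between arsenate-exposed and unexposed cultures of Saccharomyces cerevisiae S288C on 11 arrays with 2 channels each. Per the labels, the arsenate concentration was 2 μM, the medium held 100 μM phosphate (low phosphate) or 1 mM phosphate (high phosphate), and RNA was taken at 4, 8 and 10 h. Low phosphate had 2 arrays at each time. High phosphate had 2 arrays at 4 h, 2 at 8 h and 1 at 10 h. On every array the RNA of the arsenate culture carried Cy5 and that of the control culture carried Cy3. A preference of a gene for 1 dye is thus part of every ratio. If constant, it cancels in differences between times of a condition. Between conditions, which differed in array design, it cancels only if it is equal on both designs, which was not tested. The labels do not say whether replicates were separate cultures or whether arrays shared a control culture. A p-value of a gene therefore measures only the spread between these arrays, which the fit pulled toward a value pooled over all genes. List tests at a preset correlation compare genes with other genes, and the permutation test counts arrangements of labels. Very small p-values of lists are therefore not evidence of that size from the arrays. The number of arrays limits the precision of every value.

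The deposited values were taken as log2 ratios of the channels of each array, normalized by the authors. The labels state that spots with a flag value of 0 were used for normalization; the method, the scanner, the software, the log base, the direction of the ratio and the centring are not given in the sources used here. Base 10 was ruled out because ratios of the size found would exceed what a scanner can record, and base 2 rather than e was taken without a statement of it. The direction arsenate over control was taken from the dyes. The gene medians of the arrays, as deposited, were -0.07 and 0.18 at 4 h, -0.09 and -0.18 at 8 h and 0.04 and 0.08 at 10 h for low phosphate. For high phosphate they were -0.14 and -0.12 at 4 h, -0.14 and -0.12 at 8 h and -0.01 at 10 h. Intensities and backgrounds were not used here, so signal over background is unknown.

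The arrays came in 2 tables on different array designs, 1 for all low phosphate arrays and 1 for all high phosphate arrays. Phosphate and array design therefore cannot be told apart. Each table had 10807 spots, of which 6999 to 9412 had a value on an array. For high phosphate, 9271 spots named 1 of 5636 genes, all found in the reference gene table, and 3610 genes had more than 1 spot. For low phosphate, 9202 spots named 1 of 5598 genes, of which 5593 were found there, and 3588 genes had more than 1 spot. Of the 9202 spots named in both tables, 9194 named the same gene. The 1536 and 1605 spots without a gene name were left out of the tests. Of these, 96 had a value on every high phosphate array and 152 on every low phosphate array, and 0 changed at least 2-fold in 1 direction on every array. The share of blank spots ran from 12.9% to 25.9% for low phosphate and from 20.4% to 35.2% for high phosphate. The genome build behind the spots is not given, so no positions are printed.

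Spots of a gene were averaged on each array. Genes with a value on at least 1 array of every group in a comparison were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested, a threshold of 0.05 and two-sided tests. The arrays of a phosphate condition shared 1 estimate of spread, with 3 residual degrees of freedom for low phosphate and 2 for high phosphate, and the lone 10 h array at high phosphate was assumed to vary like the others. For each condition the mean of each time, the mean of the 3 times, 10 h minus 4 h and any difference between times were tested on 5185 genes at low and 4816 genes at high phosphate. The difference between conditions, low minus high phosphate averaged over matched times, was tested on 4841 genes. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9. Standard errors (SE) are limma's moderated ones, and standard deviations (SD) are between the 2 arrays of a time. Moderation pulled the spread of each gene toward a value pooled over all genes. The prior degrees of freedom, which set the weight of that value, were 15.5 at low phosphate and 1.72 at high phosphate. For low minus high phosphate they were 3.49. At low phosphate an SE is thus mostly the pooled value and can be too small for genes whose arrays vary widely, such as ARR3.

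The 29 gene lists, the rule for naming genes, the genes always eligible, the comparisons and the tests were fixed before the data were examined. Lists with at least 5 genes measured on every array were tested with camera from limma at a preset correlation between genes of 0.01, which compares a list with the other genes, with adjustment over the lists. As alternatives the correlation was estimated from the residuals, and fry was run, which tests whether the genes of a list move 1 way on balance and not against other genes. With an estimated correlation 0 lists passed for either condition. Camera tests of lists at single times were added after the data were seen. Lists were compared between conditions by an exact permutation test of the phosphate labels within each time, on the mean percentile rank of a list within an array. It had 108 arrangements, and 0.00926 was the smallest p it could give. The pattern for ribosomal proteins also caught RPP1, a subunit of nuclear ribonuclease P (0.09 at low phosphate, adjusted p = 0.445).

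Named genes were chosen by rule. For the mean of the times, 10 h minus 4 h and low minus high phosphate, the 10 largest rises and the 10 largest falls that passed were taken, with the same sign on every array for the mean of the times. Where fewer than 3 passed in a direction, the 5 with the largest moderated t were named as not having passed. The 2 members with the highest and the 2 with the lowest moderated t could be named from each list that passed. Always eligible were ARR1, ARR2, ARR3, YCF1, FPS1, PHO84, PHO89, PHO5, SPL2, PHO81, VTC3, YAP1, MET3, MET14, GSH1, RPN4, HSP12, CTT1, HSP26 and TDH3.

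Whether the replicate number paired the arrays was checked by correlating, across genes, the difference between replicates at 1 time with that at another. At low phosphate the correlations were 0.109 for 4 and 8 h, 0.136 for 4 and 10 h and 0.190 for 8 and 10 h, over 4811, 4758 and 5141 genes that are not independent replicates. At high phosphate the only pair of times gave -0.0245. The low phosphate arrays were therefore also fitted with the replicate number as a block, and blocked values stand beside a result where they change its call. Before use, the fits were tested on simulated data with 50 changed genes of each of 4 sizes. For the mean of the times, 50 of 50 genes changed by 0.5 and 50 of 50 changed by 1 were recovered at low phosphate. At high phosphate the numbers were 6 and 32 of 50, with 45 and 49 at sizes of 2 and 4. For 10 h minus 4 h, 42 of 50 genes changed by 1 were recovered at low and 0 of 50 at high phosphate. For low minus high phosphate 46 of 50 were recovered. Genes left unchanged were called 4 to 8 times per comparison, of at least 4616. The simulated noise was independent for each gene and array, without shifts of whole arrays or correlation between genes. These numbers therefore do not give the rate of false calls on the real arrays.

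Alternatives were centring or scaling of the arrays, the median over spots, each spot tested on its own, genes measured on every array, robust empirical Bayes, array weights, the replicate block, a 2-fold rule without a test and each array left out in turn. Chosen after seeing the data were the use of only those values whose spots lay within 0.5 of each other, camera on ranked statistics of every gene tested, low minus high phosphate at single times or without 8 h, and the low phosphate mean without 8 h. The closing section gives their effect.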

Results

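The series followed yeast exposed to arsenate, an analogue of phosphate that enters cells through phosphate carriers, in media poor or rich in phosphate. RNA abundance in arsenate cultures relative to untreated cultures was measured on 11 arrays, 6 at low phosphate (2 each at 4, 8 and 10 h) and 5 at high phosphate (2 at 4 h, 2 at 8 h and 1 at 10 h). Every ratio below is a log2 ratio of arsenate over control, so 1 is a doubling and -1 a halving. The arrays held values for 4484 to 5451 genes each. Replicates at low phosphate correlated across genes at 0.767, 0.936 and 0.836 for 4, 8 and 10 h. At high phosphate the correlations were 0.547 at 4 h and 0.199 at 8 h, and 10 h had no replicate. Genes are not independent replicates, so these describe the arrays only.

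**Figure D1:**
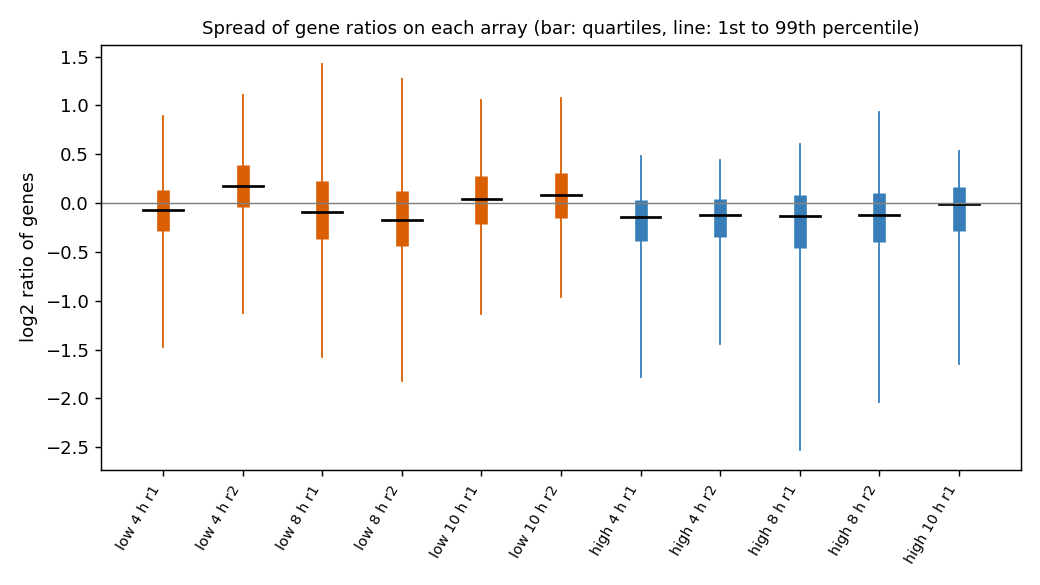
Log2 ratios of genes (vertical axis, arsenate over control) on each of the 11 arrays (horizontal axis), with orange for low and blue for high phosphate; black lines are medians, bars span the quartiles and thin lines leave out the outer 1% at each end. Medians lay between -0.18 and 0.18, and the lower ends of the thin lines were lowest, at -2.53 and -2.03, on the high phosphate arrays at 8 h.

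The first comparison asked which transcripts differed in abundance with arsenate at low phosphate, averaged over the 3 times. ARR2, which encodes arsenate reductase, rose by 6.94 (SE 0.08), and ARR3, the arsenite exporter encoded next to it, rose by 5.08 (SE 0.24), each higher on 6 of 6 arrays. FRM2, a nitroreductase-like protein, rose by 6.49 (SE 0.15). ARR1, the activator of ARR2 and ARR3, rose by 0.37 (SE 0.07, adjusted p = 0.000294), while the vacuolar conjugate transporter YCF1 stood at 0.07 (SE 0.07, adjusted p = 0.469) and the channel FPS1 at -0.01 (SE 0.07, adjusted p = 0.936). The sulfate permease SUL1 rose by 2.19 (SE 0.08), the methionine permease MUP1 by 1.47 (SE 0.08), and the sulfate-activating enzymes MET3 and MET14 by 0.80 (SE 0.09) and 0.92 (SE 0.07). GSH1, the first enzyme of glutathione synthesis, rose by 0.55 (SE 0.07). The other large rises were RPS18B at 1.26, RPS9A at 1.19 and RPS0B at 1.11, which encode ribosomal proteins, the membrane protein RTA1 at 1.25 (SE 0.08) and the cell wall mannoprotein CWP1 at 1.18 (SE 0.08). The largest falls were the nucleotidase PHM8 at -1.91 (SE 0.08), YLR161W at -1.86 (SE 0.10), the small chaperone HSP26 at -1.73 (SE 0.07), BDH2 at -1.60, the heat shock protein SSA4 at -1.47, GND2 at -1.44, SGA1 at -1.42, ATG39 at -1.29, ULI1 at -1.21 and DDR2 at -1.12. The catalase CTT1 fell by 1.02 (SE 0.07), HSP12 fell by 0.79 (SE 0.08), and the proteasome regulator RPN4 fell by 0.27 (SE 0.07, adjusted p = 0.00515). YAP1, the oxidative stress regulator, stood at -0.04 (adjusted p = 0.644) and the glycolytic TDH3 at -0.04 (adjusted p = 0.664). Of 5185 genes, 992 were higher and 1044 lower in the limma test. Without 8 h the numbers were 740 and 408. The balance turned on which 4 h array was used, with 1496 higher and 833 lower without the first and 877 and 1428 without the second. Without the first or second 8 h array they were 653 and 795 or 778 and 668, and without the first 10 h array 720 and 687. Leaving out 8 h also moved HSP26 to -0.75, GND2 to -0.46, DDR2 to -0.55, HSP12 to -0.44, CTT1 to -0.58 and RPN4 to -0.42, and RPN4 gave adjusted p = 0.0702 without the first 10 h array, with a range over its alternatives from 0.00102 to 0.0702.

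Genes that respond to phosphate starvation were lower on average at low phosphate but not at each time. Of 21 measured members of the PHO regulon, 0 rose and 17 fell (0 and 19 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 1.72e-08, adjusted p = 0.502 with an estimated correlation). The acid phosphatase PHO5 fell by 0.76 (SE 0.07), PHM6 fell by 0.92 (SE 0.07), SPL2 by 0.39 (SE 0.08), the phosphate carrier PHO84 by 0.29 (SE 0.07), the kinase inhibitor PHO81 by 0.22 (SE 0.07, adjusted p = 0.016) and the polyphosphate synthesis protein VTC3 by 0.21 (SE 0.07, adjusted p = 0.0222). The sodium-coupled carrier PHO89 stood at -0.18 (SE 0.07, adjusted p = 0.0554). Without 8 h PHO5 (0.32, adjusted p = 0.0185), VTC3 (0.31, adjusted p = 0.0224) and PHO89 (0.46, adjusted p = 0.0008) passed as higher. PHM6 stood at 0.22, SPL2 at 0.04, PHO84 at 0.25 and PHO81 at 0.00 in that fit, and the list gave adjusted p = 0.464 in the other direction. PHO89 passed as lower without the second 4 h array (adjusted p = 0.022), after centring (0.0178), on genes measured on every array (0.0496) and with robust empirical Bayes (0.0442), while PHO81 and VTC3 failed without the second 8 h array or without either 10 h array (0.0907 to 0.119 for PHO81 and 0.0900 to 0.204 for VTC3). VTC3 also failed after scaling of the arrays (0.180). Over all alternatives, in either direction, adjusted p ran from 0.0008 to 0.582 for PHO89, from 0.0022 to 0.988 for PHO81, from 0.00321 to 0.204 for VTC3 and from 1.18e-30 to 0.0185 for PHO5. The 8 phosphate transporters as a list did not pass, with 1 higher and 2 lower (1 and 3 adjusted over the list alone), a median of -0.03 and adjusted p = 0.596.

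Among the other lists at low phosphate, 25 of 30 sulfur assimilation genes rose and 0 fell (26 and 0 adjusted over the list alone; median 0.59, camera adjusted p = 2.94e-18). Of 136 cytosolic ribosomal protein genes 133 rose and 0 fell (133 and 0 adjusted over the list alone; median 0.73, adjusted p = 9.36e-77). Ribosome biogenesis had 75 of 97 genes higher and 0 lower (80 and 0 over the list alone; median 0.26, adjusted p = 3.22e-13), among them the helicase DBP2 at 0.59 (SE 0.07) and the RNA polymerase I subunit RPA135 at 0.52 (SE 0.07). These lists gave adjusted p = 0.455, 0.455 and 0.636 with an estimated correlation. The general stress response fell, with 27 of 29 genes lower and 0 higher (28 and 0 over the list alone; median -0.62, adjusted p = 2.94e-18, adjusted p = 0.455 with an estimated correlation). Of the trehalose and glycogen genes 16 of 20 fell and 1 rose (17 and 1 over the list alone; median -0.51, adjusted p = 1.25e-09, adjusted p = 0.455 with an estimated correlation), including the phosphorylase GPH1 at -1.43 (SE 0.08) and the synthase GSY1 at -1.06 (SE 0.07). Heat shock chaperones had 15 of 25 lower and 1 higher (15 and 1 over the list alone; median -0.25, adjusted p = 7.28e-08, adjusted p = 0.502 with an estimated correlation). Enzymes of the tricarboxylic acid and glyoxylate cycles had 14 of 23 lower and 0 higher (14 and 0 over the list alone; median -0.19, adjusted p = 0.000873). The respiratory chain had 15 of 40 lower and 2 higher (15 and 2; median -0.14, adjusted p = 0.00178), and glycolysis 8 of 25 lower and 2 higher (8 and 2; median -0.08, adjusted p = 0.00497), with the dehydrogenase TDH1 at -1.05 (SE 0.07) and the kinase HXK1 at -1.06 (SE 0.07). These 3 gave adjusted p = 0.636, 0.846 and 0.846 with an estimated correlation. Purine synthesis had 11 of 20 genes higher and 0 lower (13 and 0 over the list alone; median 0.18, adjusted p = 0.00178, adjusted p = 0.641 with an estimated correlation). Amino acid biosynthesis had 19 of 56 higher and 0 lower (19 and 0; median 0.12, adjusted p = 0.00353, adjusted p = 0.846 with an estimated correlation). Cell wall integrity had 14 of 29 higher and 3 lower (14 and 3; median 0.16, adjusted p = 0.00473, adjusted p = 0.846 with an estimated correlation), with the kinase KDX1 at 0.78 (SE 0.07). Without 8 h, RPA135 stood at 0.04, DBP2 at 0.31, GPH1 at -0.33, GSY1 at -0.40, TDH1 at -0.27 and HXK1 at -0.36. Leaving out 8 h also turned ribosome biogenesis (0.0466), purine synthesis (0.0466) and amino acid biosynthesis (0.435) to the other direction and ended the calls of trehalose and glycogen (0.314), the respiratory chain (0.400) and glycolysis (0.419).

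Arsenic resistance genes and histones passed at low phosphate on weaker ground. Of the 7 arsenic resistance genes 3 rose and 0 fell, over all genes and adjusted over the list alone, with a median of 0.07 and a mean of 1.75 (camera adjusted p = 0.00219, adjusted p = 0.455 with an estimated correlation). The 3 were ARR1, ARR2 and ARR3. That list failed without the first 4 h array (0.135) and after centring (0.100), and its alternatives ran from 1.85e-44 to 0.455. Histones had 8 of 10 genes higher and 0 lower (8 and 0 adjusted over the list alone; median 0.23, adjusted p = 0.00779, adjusted p = 0.641 with an estimated correlation). They failed without either 8 h array (0.0621 and 0.0783) or either 10 h array (0.0572 and 0.0902) and with the replicate block (0.0637), over a range from 3.98e-05 to 0.641. The remaining lists did not pass. Over all genes and then adjusted over the list alone, glutathione genes had 7 and 8 higher and 6 and 6 lower of 23 (adjusted p = 0.596), oxidative stress genes 3 and 3 higher and 10 and 10 lower of 26 (median -0.15, adjusted p = 0.0826), and the proteasome 1 and 0 higher and 2 and 1 lower of 34 (adjusted p = 0.772). By the same counts, mitochondrial ribosomal proteins had 7 and 4 higher and 3 and 3 lower of 56 (0.835), the iron regulon 4 and 4 higher and 5 and 5 lower of 25 (0.772), ergosterol synthesis 7 and 8 higher and 2 and 4 lower of 27 (0.886), and the cell cycle list 10 and 10 higher and 4 and 4 lower of 38 (0.299, and 0.00138 without 8 h in a range from 0.00138 to 0.963). DNA damage genes had 0 and 0 higher and 4 and 2 lower of 17 (0.248), and reference genes 1 and 0 higher and 1 and 0 lower of 13 (0.533). Signs differed for the zinc regulon (4 and 4 higher and 3 and 3 lower of 14), with a median of 0.07, a mean of 0.00 and a test directed down (0.903), and for hexose transport (5 and 5 higher and 5 and 6 lower of 18), with a median of -0.01, a mean of -0.04 and a test directed up (0.788). Of 18 measured genes of meiosis and sporulation, 2 were higher and 11 lower (2 and 12 adjusted over the list alone; median -0.26), too few of them on every array for camera. Transcripts of the mitochondrial genome were not measured in this table. Of the lists that passed, fry lost amino acid biosynthesis (0.0643), the respiratory chain (0.112) and cell wall integrity (0.0640) and passed the others.

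**Figure D2:**
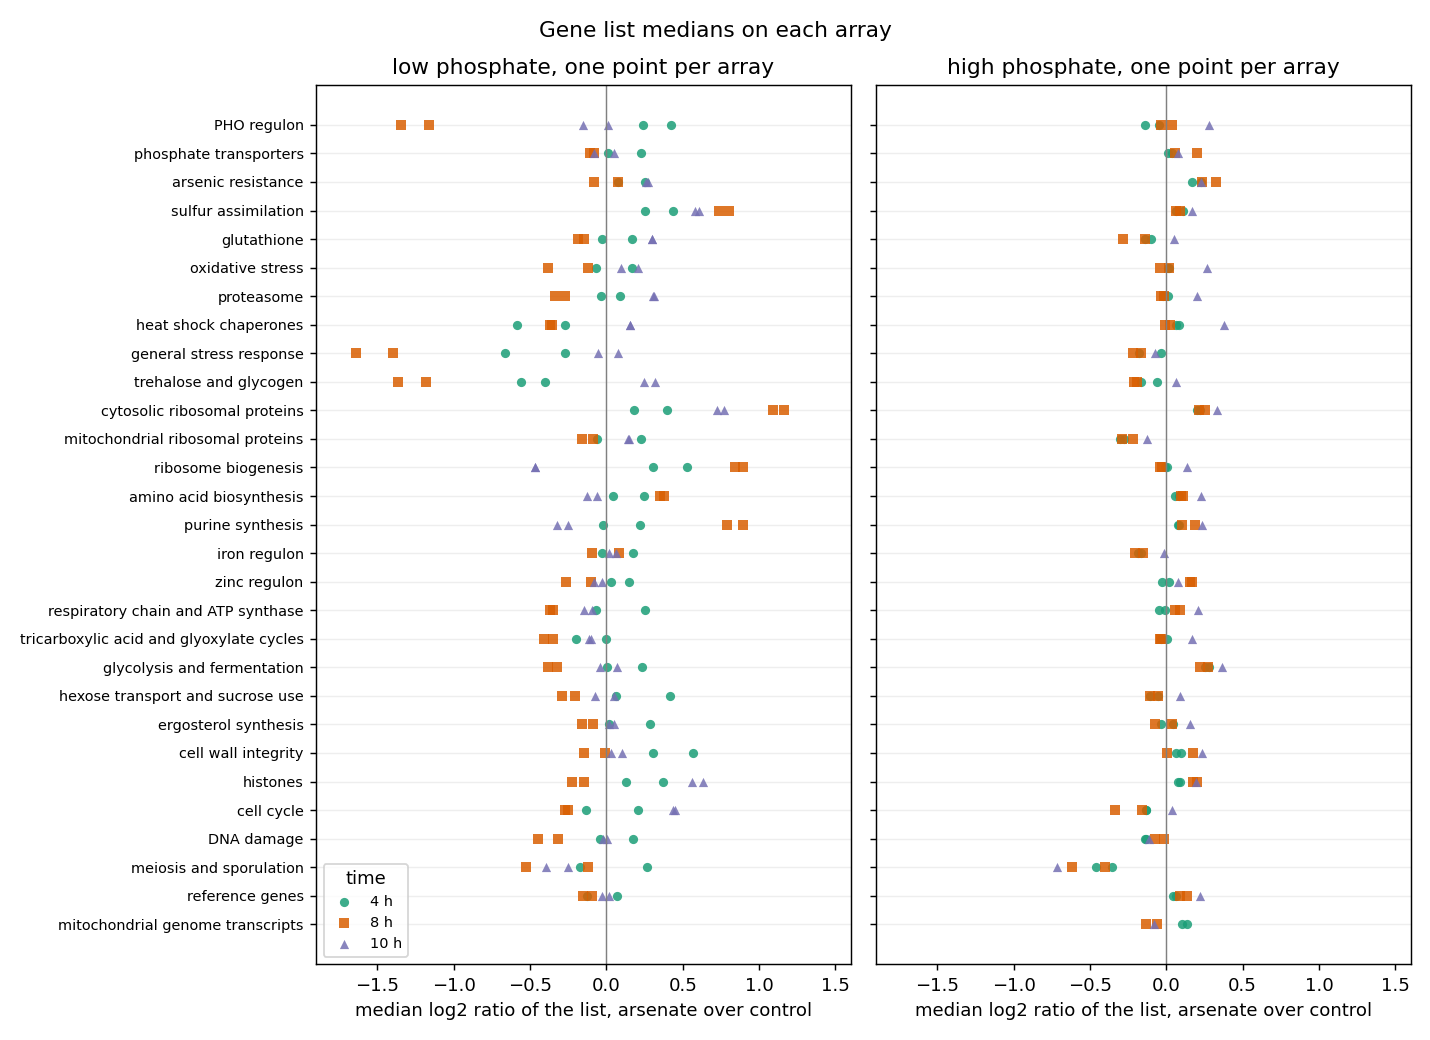
Median log2 ratio (horizontal axis, arsenate over control) of each gene list (vertical axis), 1 point per array, at low phosphate (left) and high phosphate (right), with shape and colour for 4, 8 and 10 h. At low phosphate and 8 h the general stress response had a median of -1.40 over genes and cytosolic ribosomal proteins 1.11, while at high phosphate all list medians averaged over times lay between -0.60 and 0.33.

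At 4 h of low phosphate the question was the early response. ARR2 rose by 7.35 (SD 0.09, n = 2), FRM2 by 7.02 (SD 1.31, n = 2), ARR3 by 4.97 (SD 1.41, n = 2) and SUL1 by 2.37 (SD 0.26, n = 2). Chaperones of the heat shock response were among the lowest. SSA4 fell by 2.91 (SD 0.33), BTN2 and HSP42, which gather misfolded proteins, fell by 2.57 (SD 0.01) and 2.55 (SD 0.06), and the mitochondrial disaggregase HSP78 fell by 2.39 (SD 0.05). GRE2 fell by 1.90 (SD 0.29), CTT1 by 1.18 (SD 0.10) and RPN4 by 0.84 (SD 0.17). Of the heat shock list 0 rose and 13 fell (0 and 14 adjusted over the list alone; median -0.43, adjusted p = 4.11e-14). The general stress response had 0 higher and 15 lower (2 and 16 over the list alone; median -0.49, adjusted p = 1e-09), and trehalose and glycogen 2 higher and 12 lower (2 and 12; median -0.52, adjusted p = 4.72e-06). All 3 gave adjusted p = 0.799 with an estimated correlation. Higher lists were sulfur assimilation with 14 up and 0 down (17 and 0 over the list alone; median 0.33, adjusted p = 1.13e-07), cytosolic ribosomal proteins with 46 and 1 (72 and 1; median 0.31, adjusted p = 4.1e-09), ribosome biogenesis with 65 and 0 (79 and 0; median 0.42, adjusted p = 3.72e-15) and cell wall integrity with 19 and 0 (20 and 0; median 0.40, adjusted p = 2.35e-07). With an estimated correlation their adjusted p = 0.799, 0.924, 0.815 and 0.889. PHO5 rose by 1.11 (SD 0.01), PHO89 by 0.98 (SD 0.12) and PHO84 by 0.38 (SD 0.15, adjusted p = 0.0244), while PHM8 stood at -2.19 on the 1 array that measured it. The PHO regulon had 9 higher and 4 lower (12 and 5 adjusted over the list alone; median 0.31, adjusted p = 0.0473, adjusted p = 0.924 with an estimated correlation). It failed without any 1 of the 6 arrays (0.188 to 0.252), with the block (0.186) and with fry (0.110), in a range from 0.0239 to 0.924. PHO84 failed without the second 4 h array (0.149) or the second 10 h array (0.0569) and with array weights (0.212), in a range from 0.0109 to 0.212. CWP1, at 0.50 (SD 0.08), failed without the second 4 h array (0.101) and with array weights (0.189), in a range from 6.62e-05 to 0.189. Of 5185 genes 763 were higher and 603 lower, and array weights brought the total from 1366 to 362. Centring the arrays, which at 4 h have medians of -0.07 and 0.18, gave 883 higher and 922 lower. Without the first 4 h array 1351 were higher and 348 lower, and without the second 299 and 791, so the majority changed direction with the array. Fry lost every list here but heat shock, at 0.0652 to 0.110.

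At 8 h the phosphate and stress genes lay far below control. PHM6 fell by 3.19 (SD 0.15, n = 2), PHM8 fell by 2.95 (SD 0.14), PHO5 fell by 2.93 (SD 0.16) and PHO84 fell by 1.36 (SD 0.12), and 20 of 21 genes of the PHO regulon fell with 0 higher (20 and 0 adjusted over the list alone; median -1.25, camera adjusted p = 7.84e-14). HSP26 fell by 3.70 (SD 0.06), GPH1 by 3.63 (SD 0.02) and GND2 by 3.41 (SD 0.10). Of the general stress response 27 fell and 0 rose (28 and 0 over the list alone; median -1.40, adjusted p = 7.94e-16), and of trehalose and glycogen 17 fell and 0 rose (18 and 0; median -1.33, adjusted p = 1.27e-11). Against these, ribosomal proteins had 134 higher and 0 lower (134 and 0 over the list alone; median 1.11, adjusted p = 9.3e-65), ribosome biogenesis 96 and 0 (96 and 0; median 0.87, adjusted p = 2.36e-37), sulfur assimilation 25 and 0 (25 and 0; median 0.71, adjusted p = 8.05e-13) and purine synthesis 18 and 0 (18 and 0; median 0.83, adjusted p = 1.45e-11). Each of these 7 lists gave adjusted p = 0.321 with an estimated correlation. RPS18B rose by 1.83 (SD 0.15), RPA135 by 1.48 (SD 0.00), the one-carbon enzyme SHM2 by 1.77 (SD 0.28), the purine enzyme ADE4 by 1.32 (SD 0.05), SUL1 by 1.95 (SD 0.07) and the methylmethionine permease MMP1 by 1.88 (SD 0.02). ARR2 rose by 7.91 (SD 0.13), FRM2 by 7.45 (SD 0.26) and ARR3 by 6.37 (SD 1.04). Amino acid biosynthesis had 32 higher and 0 lower (35 and 0 over the list alone; median 0.35, adjusted p = 2.25e-08, adjusted p = 0.681 with an estimated correlation). Lower were heat shock chaperones with 14 down and 2 up (14 and 2 over the list alone; median -0.37, adjusted p = 0.0104), the respiratory chain with 24 and 0 (28 and 0; median -0.37, adjusted p = 0.000537) and glycolysis with 14 and 0 (16 and 1; median -0.33, adjusted p = 0.00115), for which adjusted p = 0.83, 0.83 and 0.801 with an estimated correlation. TDH1 fell by 2.61 (SD 0.07), HXK1 by 2.45 (SD 0.01) and the cyclin PCL1 by 1.20 (SD 0.04). Of 5185 genes 951 were higher and 1584 lower. Centring the arrays, which have medians of -0.09 and -0.18, gave 1446 and 1181, and the total of 2535 fell to 1534 without the first 8 h array (607 higher, 927 lower) and 1380 without the second (688 and 692).

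At 10 h ribosomal proteins and ribosome biogenesis moved apart. RPS9A rose by 1.90 (SD 0.19, n = 2) and RPL9A by 1.36 (SD 0.04), and 126 ribosomal protein genes rose with 0 lower (126 and 0 adjusted over the list alone; median 0.76, adjusted p = 2.41e-41). The assembly helicase MAK5 fell by 1.18 (SD 0.10), and ribosome biogenesis had 69 lower and 1 higher (82 and 1 over the list alone; median -0.45, adjusted p = 2.99e-28). The 1 higher gene was UTP22, named after its value was seen, at 0.41 (SD 0.09, adjusted p = 0.0138). It failed without the first (0.308) or second (0.151) 10 h array, in a range from 0.00208 to 0.308. Sulfur assimilation had 20 higher and 0 lower (21 and 0 over the list alone; median 0.60, adjusted p = 7.17e-08), with SUL1 at 2.26 (SD 0.46), MMP1 at 1.62 (SD 0.05) and MET3 at 1.34 (SD 0.08). Histones had 8 higher and 0 lower (10 and 0 over the list alone; median 0.64, adjusted p = 4.79e-05), with the histone H4 gene HHF2 at 0.87 (SD 0.07). With an estimated correlation these 4 lists gave adjusted p = 0.755. Cell cycle genes had 23 higher and 1 lower (24 and 1 over the list alone; median 0.40, adjusted p = 2.11e-05, adjusted p = 0.986 with an estimated correlation), with the G1 cyclins PCL1 at 1.09 (SD 0.08) and CLN1 at 0.95 (SD 0.06). Purine synthesis had 0 higher and 9 lower (0 and 11 over the list alone; median -0.31, adjusted p = 5.85e-05, adjusted p = 0.772 with an estimated correlation). The proteasome had 15 higher and 0 lower (18 and 0 over the list alone; median 0.31, adjusted p = 0.00686, adjusted p = 0.986 with an estimated correlation). It failed without the second 10 h array (0.0717) and with fry (0.0782), in a range from 0.000846 to 0.986, and fry also lost purine synthesis and the cell cycle list (0.0686 each). CWP1 rose by 2.55 (SD 0.41), ARR2 by 5.55 (SD 0.45), FRM2 by 4.996 (SD 0.49) and ARR3 by 3.90 (SD 1.75). ARR3 gave adjusted p = 0.0538 under robust empirical Bayes, the highest over its alternatives. PHO5 fell by 0.48 (SD 0.18, adjusted p = 0.00636) but gave 0.301 without the first 10 h array, in a range from 0.000122 to 0.301, and the PHO regulon had 1 higher and 2 lower (1 and 2 over the list alone; median -0.06, adjusted p = 0.583). Of 5185 genes 1047 were higher and 662 lower. Centring gave 1041 and 1061, and the total of 1709 fell to 609 without the first 10 h array (403 higher, 206 lower) and 647 without the second (375 and 272).

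**Figure D3:**
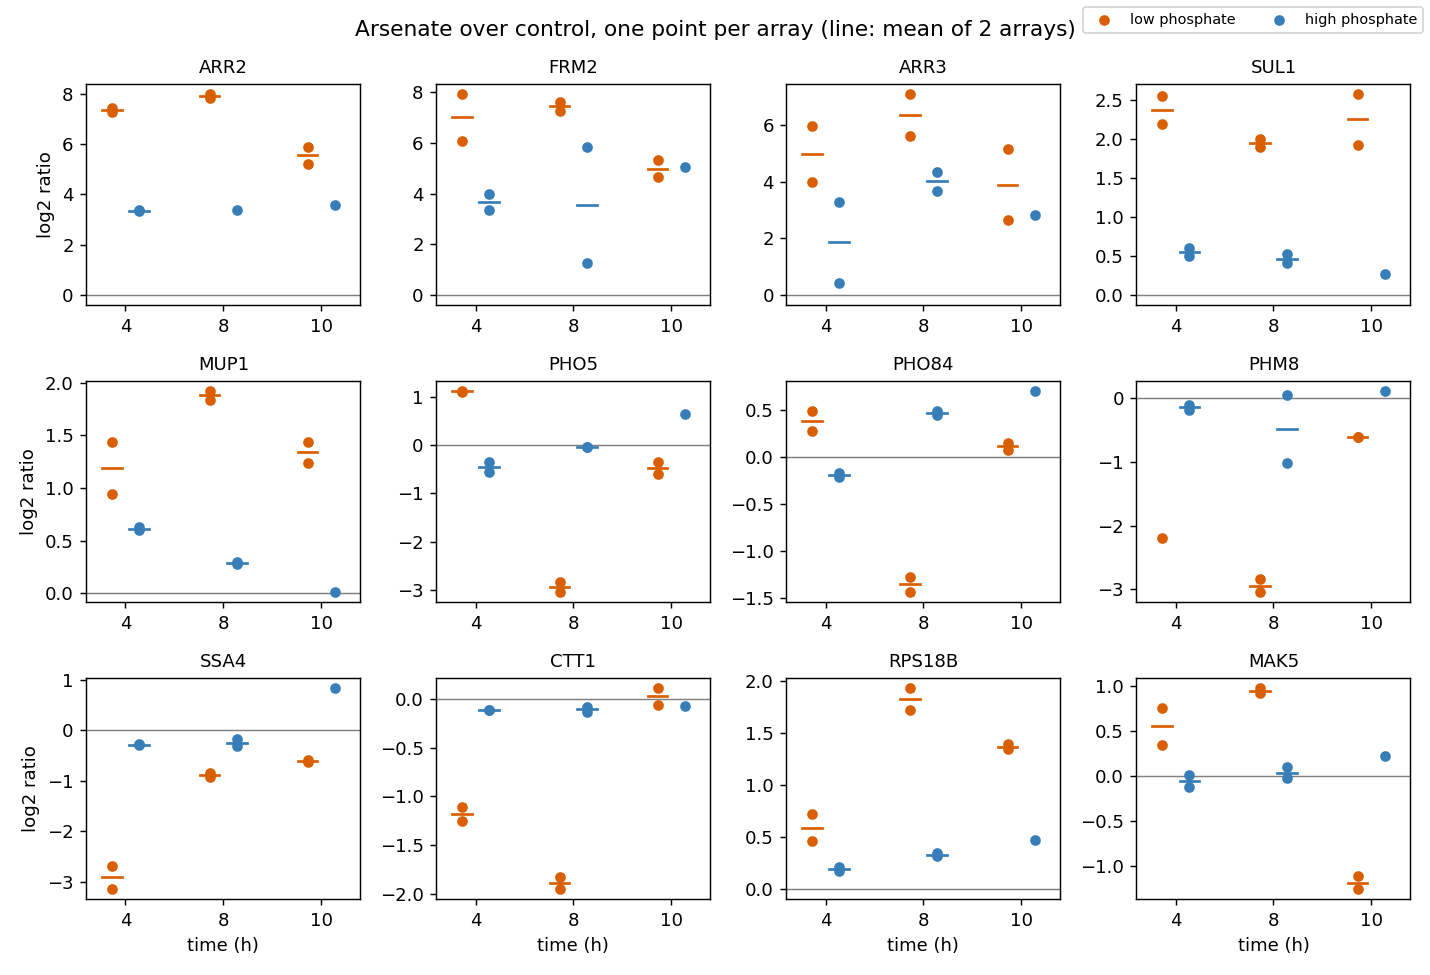
Log2 ratios (vertical axis, arsenate over control) of 12 genes at 4, 8 and 10 h (horizontal axis), 1 point per array, orange for low and blue for high phosphate, with a line at the mean of 2 arrays. PHO5 at low phosphate stood at 1.11, -2.93 and -0.48 at the 3 times, and ARR2 lay above 3 on every array that measured it.

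The change of the low phosphate response over time was tested as 10 h minus 4 h, where a constant dye effect cancels. Chaperone genes moved from far below control to near it, with BTN2 up by 2.89 (SE 0.17), HSP78 by 2.72 (SE 0.17) and HSP42 by 2.60 (SE 0.17). The other largest rises were YLR161W at 3.45 (SE 0.26), YNL194C at 3.39 (SE 0.45), the choline transporter-like PNS1 at 3.14, PHM7 at 2.68, the reductase GRE2 at 2.61, the sphingolipid base translocator RSB1 at 2.60 and the kinase PRR2 at 2.53. The largest falls were OSI1 at -2.74 (SE 0.39), the proton pump PMA2 at -2.64, BSC1 at -2.62, UIP4 at -2.53, RGM1 at -2.41, the mannoprotein TIR3 at -2.26, the permease SEO1 at -2.25, the cytidine deaminase CDD1 at -2.25, GUP2 at -2.21 and ANB1 at -2.20. ARR2 fell by 1.81 (SE 0.20), PHO5 by 1.59, PHO89 by 1.05 and MAK5 by 1.73, while CTT1 rose by 1.20, RPL9A by 1.17, PGM2 by 1.42 and PCL1 by 1.11. ARR3 stood at -1.08 (SE 0.60, adjusted p = 0.179). With the block it passed (1.38e-06) at the same value of -1.08. The prior degrees of freedom were infinite in that fit, so every gene received 1 common spread and that of ARR3 itself was not used. This pass is therefore not evidence from the ARR3 arrays. ARR3 stood at -1.08 without the first or second 8 h array, at -2.07 without the first 4 h array and at -2.32 without the second 10 h array. Those fits left 1 array at the time concerned. Under robust empirical Bayes YNL194C (0.0772), OSI1 (0.273) and CDD1 (0.0765) failed, the highest values of their ranges from 5.72e-60, 4.94e-17 and 1.15e-26. Without the second 4 h array YNL194C stood at 2.14 and CDD1 at -1.45. Of 5185 genes 939 rose and 799 fell, and 2978 differed between any of the 3 times. The majority changed direction with the 4 h array, with 693 higher and 1160 lower without the first and 1434 and 642 without the second. The 1738 of 10 h minus 4 h became 1001 without the first 10 h array (532 higher, 469 lower) and 980 without the second (463 and 517).

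Ribosome biogenesis fell most by list in that contrast, with 0 higher and 89 of 97 lower (0 and 91 adjusted over the list alone; median -0.88, camera adjusted p = 1.42e-35), while ribosomal proteins had 70 of 136 higher and 0 lower (75 and 1 over the list alone; median 0.48, adjusted p = 1.63e-10). Heat shock chaperones had 14 higher and 1 lower (16 and 1; median 0.56, adjusted p = 7.25e-07), the general stress response 11 and 3 (13 and 3; median 0.30, adjusted p = 0.00242), trehalose and glycogen 12 and 2 (12 and 2; median 0.78, adjusted p = 6.37e-05), the cell cycle list 17 and 2 (18 and 2; median 0.37, adjusted p = 0.00514) and purine synthesis 0 and 11 (1 and 13; median -0.51, adjusted p = 0.00193). The median over all genes was 0.07. With an estimated correlation every list of this contrast that passed gave adjusted p = 0.966. Fry kept only heat shock chaperones and ribosome biogenesis, at 0.0483, and lost the other 5 at 0.0965 to 0.227. The proteasome (8 higher, 0 lower, 2 and 0 over the list alone; median 0.26, adjusted p = 0.0462), the respiratory chain (1 higher, 10 lower, 1 and 10; median -0.19, adjusted p = 0.043) and cell wall integrity (3 higher, 10 lower, 3 and 10; median -0.36, adjusted p = 0.0462) passed narrowly. They failed with the block (0.106, 0.0961 and 0.104), with fry (0.227, 0.336 and 0.336) and without either 8 h or either 10 h array, at 0.0982 to 0.155, 0.0880 to 0.0987 and 0.0774 to 0.120. Their alternatives ran from 0.00884, 0.00838 and 0.0139 to 0.966.

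At high phosphate the same question, averaged over the times, gave values of the same sign for the arsenic genes but no call. ARR2 stood at 3.45 (SE 0.07, adjusted p = 0.0678) with 4 of 4 arrays higher and ARR3 at 2.91 (SE 0.51, adjusted p = 0.0717) with 5 of 5 higher. FRM2 was higher on 5 of 5 arrays, with means of 3.67 (SD 0.47, n = 2), 3.57 (SD 3.23, n = 2) and 5.07 (n = 1) at 4, 8 and 10 h and adjusted p = 0.0772. YCF1 stood at 0.39, PHO84 at 0.33, the sulfur enzymes MET17 and CYS4 at 0.53 and 0.40, GSH1 at 0.45, the fermentation enzymes PDC1 and ADH1 at 0.76 and 0.58, TDH3 at 0.42, the ribosomal proteins RPL41A and RPL41B at 0.52 and 0.54 and the actin gene ACT1 at 0.26, with adjusted p from 0.0678 to 0.0788. Highest and lowest by moderated t, none of which passed, were ARR2, OLI1 (0.84), YML131W (0.62), ADH1 and YER138W-A (0.87), and YAE1 (-1.32), DFP1 (-1.58), ATG12 (-1.17), PAU2 (-1.50) and FCY22 (-0.94). Among mitochondrial ribosomal proteins MRPL25 stood at -0.68 and MRP51 at -0.39. With limma 0 of 4816 genes passed, while 1630 had an unadjusted p under 0.05. Without the first or the second 8 h array, whose values correlated at 0.199, 1260 (327 higher, 933 lower) or 1255 (250 and 1005) genes passed, and each of these 24 genes passed in 1 or both of these fits at 0.00329 to 0.0466, within a range over all alternatives from 0.000425 to 0.341. The spread in these 2 fits came from the 4 h pair alone, and where it came from the 8 h pair alone, without the first or second 4 h array, 0 genes passed. Using only values whose spots lay within 0.5 of each other, 727 of 1935 passed, 421 higher and 306 lower, with YCF1 (0.00189), CYS4 and GSH1 (0.000922), TDH3 (0.00149), ACT1 (0.00411), MRP51 (0.00275) and MET17, YML131W, PDC1, RPL41A and RPL41B (0.000425) among them. A rule of at least 2-fold on every array without a test gave 1 gene, FRM2.

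By list, relative to the other genes, whose median at high phosphate was -0.12, the highest were ribosomal proteins and glycolysis. With 0 genes passing over all genes in any list, the counts here are adjusted over the list alone. Of 135 ribosomal protein genes 94 were higher and 0 lower (median 0.25, camera adjusted p = 4.49e-34, adjusted p = 0.222 with an estimated correlation). Of 26 glycolysis genes 16 were higher and 1 lower (median 0.33, adjusted p = 7.68e-10). Sulfur assimilation had 10 higher and 2 lower of 29 (median 0.04, adjusted p = 0.000866), heat shock chaperones 6 and 1 of 24 (median 0.13, adjusted p = 1.1e-05), cell wall integrity 6 and 1 of 28 (median 0.14, adjusted p = 3.7e-05) and reference genes 3 and 1 of 13 (median 0.10, adjusted p = 0.00699). Amino acid biosynthesis (median 0.09, adjusted p = 8.15e-09), purine synthesis (median 0.17, adjusted p = 9.34e-07), the respiratory chain (median 0.04, adjusted p = 0.0012), the tricarboxylic acid cycle (median 0.07, mean -0.00, test up, adjusted p = 0.00848) and the PHO regulon (median 0.07, mean -0.00, test up, adjusted p = 0.00693) passed with 0 genes in either direction. Mitochondrial ribosomal proteins passed downward, also with 0 genes (median -0.24, adjusted p = 2.72e-05). For all of these from glycolysis on, adjusted p = 0.223 with an estimated correlation. Histones had 1 higher and 1 lower (median 0.16, adjusted p = 0.00613, adjusted p = 0.266 with an estimated correlation) and arsenic resistance genes 3 and 0 of 7 (median 0.16, adjusted p = 0.0158, adjusted p = 0.321 with an estimated correlation). Proteasome genes (median 0.00, mean -0.00, test up, adjusted p = 0.0292) and ribosome biogenesis (median 0.01, mean -0.01, test up, adjusted p = 0.0158) passed with 0 genes, and gave adjusted p = 0.241 and 0.34 with an estimated correlation. Transporters (1 and 0; median 0.03, adjusted p = 0.0382), oxidative stress (2 and 3; median 0.03, adjusted p = 0.0292), the zinc regulon (0 and 0; median 0.01, adjusted p = 0.032) and ergosterol synthesis (0 and 0; median 0.01, adjusted p = 0.0382) were near the threshold, with adjusted p = 0.266, 0.331, 0.266 and 0.364 with an estimated correlation. Each of these 4 failed without the first 8 h array (0.115, 0.0724, 0.0530 and 0.0724), transporters also without the first or second 4 h array (0.0602 and 0.0832) and the zinc regulon without the second (0.0725), and the lowest of their alternatives were 0.0127, 0.00682, 0.0170 and 0.0204. Not passing were glutathione (0.499), general stress (0.866), trehalose and glycogen (0.979), iron (0.499), hexose transport (5 and 3, 0.196), cell cycle (0.866), DNA damage (1 and 2, 0.866) and mitochondrial genome transcripts (1 and 3 of 8, 0.906). Of these, general stress (median -0.12), trehalose and glycogen (-0.14), DNA damage (-0.19), mitochondrial genome transcripts (-0.14) and hexose transport (-0.04) had tests directed up. Of 9 measured genes of meiosis and sporulation 0 were higher and 8 lower (median -0.60), with no camera test. With fry 11 lists passed. It lost the PHO regulon (adjusted p = 0.0542), phosphate transporters (0.0509), arsenic resistance (0.119), oxidative stress (0.192) and the proteasome (0.127). Also lost were ribosome biogenesis (0.199), the zinc regulon (0.0832), the respiratory chain (0.0520) and ergosterol synthesis (0.0872).

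At single times of high phosphate limma also passed 0 genes, with 974, 1228 and 577 at an unadjusted p under 0.05 for 4, 8 and 10 h. With spots that agreed, 336 (101 higher, 235 lower), 430 (231 and 199) and 90 (69 and 21) passed. Without the first or the second 8 h array 502 (45 higher, 457 lower) or 564 (29 and 535) genes passed at 8 h, and 1 passed at 4 h without the first, again with the spread of the 4 h pair alone. For 10 h minus 4 h, 0 genes passed, with 214 at an unadjusted p under 0.05 and 4 with spots that agreed, among them the reductase GRE2 at 1.07 (0.0281) and PHO5 at 1.09 (0.0455). In the main test PHO5 stood at 1.09 (SE 0.16), PHO84 at 0.90 (SE 0.13), GRE2 at 1.07, SSA4 at 1.12, XYL2 at 2.38, DSC3 at 1.97, PCD1 at 5.35, MCM10 at -2.56, YGR201C at -1.44, ALR2 at -1.61, EDS1 at -1.31, SNM1 at -1.69, and the mitochondrial OLI1 and COB at -1.21 and -0.74, each with adjusted p = 0.888. Over their alternatives GRE2 ran from 0.0281 and PHO5 from 0.0455, each up to 1. ARR2 stood at 0.24. By list, the PHO regulon (2 higher and 0 lower adjusted over the list alone; median 0.32, adjusted p = 0.000543) and heat shock chaperones (1 and 0; median 0.27, adjusted p = 0.000134) stood higher on the 1 array of 10 h than at 4 h and mitochondrial genome transcripts lower (0 and 1; median -0.19, adjusted p = 0.00233), against a median of 0.14 over all genes. Each gave adjusted p = 0.588 with an estimated correlation. That array has no spread of its own, so a property of the array cannot be told from a change with time. The numbers of lists became 5 without the second 8 h array. Any difference between times gave 0 genes, with 283 at an unadjusted p under 0.05, 75 without the second 8 h array and 2 with spots that agreed.

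Whether the response differed with phosphate was tested directly, as low minus high phosphate at matched times, although the array design differed with it. ARR2 was higher at low phosphate by 3.49 (SE 0.14, adjusted p = 0.000103), the sulfate permease SUL1 by 1.76 (SE 0.14) and MMP1 by 1.24 (SE 0.09). ARR3, at 2.18 (SE 0.70, adjusted p = 0.0529), and FRM2, at 2.38 (adjusted p = 0.0536), did not pass. The largest negative differences were PHM8 at -1.75 (SE 0.21), the chaperones SSA4 at -1.57 (SE 0.10), HSP104 at -1.45 (SE 0.15), HSP42 at -1.40 (SE 0.08) and HSP78 at -1.23 (SE 0.09), GPH1 at -1.23 (SE 0.11), HXK1 at -1.20 (SE 0.10), AIM17 at -1.04, TDH1 at -1.02 and MSC1 at -0.996. CTT1 stood at -0.91 (SE 0.08), PHO5 at -0.82 (SE 0.09), PHO84 at -0.61 (SE 0.08), TDH3 at -0.46 (SE 0.10, adjusted p = 0.0128) and YCF1 at -0.32 (SE 0.08, adjusted p = 0.026). The largest positive differences after ARR2 were THI12 at 2.59, PCD1 at 2.34, RED1 at 2.12, YNR066C at 2.08, HAP3 at 2.01, SWM2 at 1.87, FAR10 at 1.84, TDA6 at 1.79 and PAU2 at 1.76, with adjusted p from 0.0011 to 0.0165. Several of these rested on a very low value of 1 high phosphate array, such as -6.06 for PCD1 at 4 h, -5.53 for THI12, -4.41 for HAP3 and -4.12 for RED1 at 8 h and -4.46 for SWM2 at 10 h. Of 4841 genes 918 were higher and 238 lower at low phosphate, in a fit that assumed equal spread in both conditions. With each array centred the numbers were 777 and 528. The total of 1156 became 591 (448 higher, 143 lower) or 681 (542 and 139) without the first or second low 8 h array and 758 (607 and 151) without the first high 4 h array. Without the first or second low 10 h array it became 680 (542 and 138) or 679 (519 and 160).

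Single times gave other values. At 4 h alone PHO5 (1.56) and PHO84 (0.58) passed as higher at low phosphate, and TDH1 stood at 0.32. The calls of MMP1 (0.04), RED1 (0.77), HAP3 (0.87), SWM2 (0.74), GPH1 (-0.51), MSC1 (-0.80), YCF1 (-0.22) and TDH3 (-0.43) ended there. At 8 h alone those of PCD1 (0.12), YNR066C (0.94), SWM2 (0.34) and FAR10 (0.86) ended. Without 8 h PHO5 stood at 0.22 and PHO84 at -0.01 (adjusted p = 0.975). Without 8 h the calls of GPH1 (-0.30, 0.187), TDH1 (-0.32, 0.192), MSC1 (-0.38, 0.343), TDH3 (0.0946) and YCF1 (0.190) ended, and THI12 stood at 1.27, RED1 at 1.00, HAP3 at 0.92, PAU2 at 0.87, HXK1 at -0.52 and CTT1 at -0.48. At 10 h alone, where high phosphate has 1 array, AIM17 stood at 0.17, MSC1 at 0.04 and CTT1 at 0.10. The calls of THI12 (0.86), PCD1 (0.87), RED1 (1.24), YNR066C (0.88), HAP3 (0.97), FAR10 (0.75), TDA6 (0.55), PAU2 (0.22), PHM8 (-0.73), HSP104 (-0.47), HSP78 (-0.12), GPH1 (-0.09), HXK1 (-0.13), TDH1 (-0.95), PHO84 (-0.59), YCF1 (-0.26) and TDH3 (-0.26) ended there too. YCF1 also failed without the first or second low 8 h array (0.0539 and 0.0757), the first or second low 10 h array (0.0676 and 0.0642) or the first high 4 h array (0.0736), and with the block (-0.30, 0.0694), in a range from 0.00341 to 0.386. ARR3 passed with the block (2.47, 0.00529) and without the first low 4 h array (0.0498), the first low 10 h array (0.0461), the first high 4 h array (0.0261) or the first or second high 8 h array (0.0130 and 0.0261), in a range from 0.00529 to 0.695. FRM2 passed with the block (2.71, 0.0326), without the first or second high 8 h array (2.48e-05 and 0.00209) with array weights (0.0162), at 8 h alone (3.88, 0.0451) and without 8 h (1.64, 0.0266), but stood at -0.07 at 10 h alone, in a range from 2.48e-05 to 0.984. In either direction, the adjusted p of GPH1 ran from 5.07e-12 to 0.837 over its alternatives, that of TDH1 from 1.51e-10 to 0.302, of MSC1 from 1.75e-11 to 0.971, of TDH3 from 9.95e-05 to 0.476, of PHO84 from 0.000242 to 0.975 and of PHO5 from 3.25e-08 to 0.276.

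Gene lists were compared between the conditions by their rank within an array, from 0 to 100, which does not depend on the scale of a table. A rank can still move with spot brightness. The mean ratio of a gene fell with its share of blank spots on the arrays of the other condition. Spearman rho was -0.341 for ratios at high phosphate and -0.246 for ratios at low phosphate. Reference genes themselves ranked 46.3 at low and 70.9 at high phosphate, so a lower rank of a list is not by itself a phosphate effect. In the exact permutation test 14 of 28 lists differed. Heat shock chaperones had a mean rank of 32.8 at low and 70.3 at high phosphate, a difference of -39.5 points when each time was matched, and glycolysis 42.6 and 81.3 (-39.4). The tricarboxylic acid cycle differed by -28.7 points, the respiratory chain by -27.8, the general stress response by -27.0 (22.3 and 49.2), reference genes by -25.0, oxidative stress by -20.4, phosphate transporters by -18.4 and ergosterol synthesis by -12.5. Sulfur assimilation ranked 11.6 points higher at low phosphate (80.1 and 68.1) and mitochondrial ribosomal proteins 15.6 points higher. Each of these had an exact permutation p = 0.00926, the smallest possible, and adjusted p = 0.0236. The zinc regulon (-15.7), the proteasome (-15.1) and arsenic resistance genes (-11.2) had adjusted p = 0.037; ranks near the top cannot show the larger ratios of ARR2. The PHO regulon, at 4.44 against 59.7 at 8 h but 64.0 against 51.1 at 4 h, did not pass (-26.8, adjusted p = 0.130), nor did ribosomal proteins (0.76, adjusted p = 0.931) or ribosome biogenesis (-0.04, adjusted p = 1). Also short of the threshold were trehalose and glycogen (-19.2, 0.104), amino acid biosynthesis (-16.9, 0.113), meiosis and sporulation (12.8, 0.130), hexose transport (-7.42, 0.136), purine synthesis (-22.0, 0.143), iron (3.75, 0.160), cell wall integrity (-10.3, 0.177), glutathione (3.65, 0.225), DNA damage (-6.72, 0.389), the cell cycle list (3.20, 0.684) and histones (-3.69, 0.738). All 14 calls ended without either low 10 h array (from 0.0598) or the high 10 h array (from 0.104), where fewer arrangements exist. Arsenic resistance also failed without the first or second low 8 h array (0.162 and 0.130) or the first or second high 4 h array (0.104 and 0.144), and the zinc regulon without 9 of the 11 arrays (0.0691 to 0.173). By median shift in place of rank, the proteasome (0.0972) and the general stress response (0.0741) failed. Over their alternatives the 14 lists ran from 0.0236 to 0.173.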

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

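The explanations below were tested after the results were seen, except the dependence on spot brightness, which was written down before. The results in this part were picked out because the response differed between times or between phosphate conditions by a test of the difference itself.

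At low phosphate 2978 genes differed between times and 1738 differed between 10 h and 4 h. By list, the medians of 10 h minus 4 h were 0.26 for the proteasome, 0.56 for heat shock chaperones, 0.30 for the general stress response, 0.78 for trehalose and glycogen, 0.48 for cytosolic ribosomal proteins, -0.88 for ribosome biogenesis, -0.51 for purine synthesis, -0.19 for the respiratory chain, -0.36 for cell wall integrity and 0.37 for the cell cycle list. With an estimated correlation each gave adjusted p = 0.966, and the proteasome, the respiratory chain and cell wall integrity also failed with the replicate block (0.106, 0.0961 and 0.104). By gene, the rises were YLR161W 3.45, YNL194C 3.39, PNS1 3.14, BTN2 2.89, HSP78 2.72, PHM7 2.68, GRE2 2.61, RSB1 2.60, HSP42 2.60, PRR2 2.53, HBN1 1.46, PGM2 1.42, CTT1 1.20, RPL9A 1.17 and PCL1 1.11. The falls were OSI1 -2.74, PMA2 -2.64, BSC1 -2.62, UIP4 -2.53, RGM1 -2.41, TIR3 -2.26, SEO1 -2.25, CDD1 -2.25, GUP2 -2.21, ANB1 -2.20, ARR2 -1.81, MAK5 -1.73, PHO5 -1.59 and PHO89 -1.05. At high phosphate the medians of 10 h minus 4 h were 0.32 for the PHO regulon, 0.27 for heat shock chaperones and -0.19 for mitochondrial genome transcripts. These rest on 1 array of 10 h, assumed to vary like the others, and gave adjusted p = 0.588 with an estimated correlation.

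Between the conditions 1156 genes differed. Higher at low phosphate were ARR2 by 3.49, THI12 2.59, PCD1 2.34, RED1 2.12, YNR066C 2.08, HAP3 2.01, SWM2 1.87, FAR10 1.84, TDA6 1.79, PAU2 1.76, SUL1 1.76, MMP1 1.24 (0.04 at 4 h only) and HBN1 0.71. Lower were PHM8 -1.75, SSA4 -1.57, HSP104 -1.45, HSP42 -1.40, HSP78 -1.23, GPH1 -1.23, HXK1 -1.20, AIM17 -1.04, TDH1 -1.02, MSC1 -0.996, CTT1 -0.91, PHO5 -0.82, PHO84 -0.61, TDH3 -0.46 and YCF1 -0.32. At 4 h only PHO5 (1.56) and PHO84 (0.58) were higher at low phosphate instead. Without 8 h PHO5 stood at 0.22 and PHO84 at -0.01, and the calls of GPH1, TDH1, MSC1, TDH3 and YCF1 ended. Further calls in both directions ended at single times, as given above. By rank within an array, sulfur assimilation differed by 11.6 points and mitochondrial ribosomal proteins by 15.6. The other lists were lower at low phosphate, with heat shock chaperones at -39.5, glycolysis -39.4, the tricarboxylic acid cycle -28.7, the respiratory chain -27.8, the general stress response -27.0, reference genes -25.0, oxidative stress -20.4, phosphate transporters -18.4, the zinc regulon -15.7, the proteasome -15.1, ergosterol synthesis -12.5 and arsenic resistance -11.2. Reference genes were among them, so an effect of phosphate on the others is not separated from the array design or spot brightness. These 14 calls ended without any 1 of the 10 h arrays, where fewer arrangements exist and the smallest adjusted p reached was 0.0598 without a low and 0.104 without the high phosphate array, so the loss follows in large part from that limit.

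At low phosphate and 8 h, phosphate and stress genes lay below control and ribosomal genes above it. A dye effect that is constant over time does not account for it, because the PHO regulon at 8 h minus the mean of 4 and 10 h had a median of -1.29, with 21 of 21 genes below 0. Centring does not account for it either, since relative to all genes the PHO regulon lay at -1.07 on the higher of both 8 h arrays. A control culture closer to running out of phosphate than the arsenate culture is a candidate explanation. The PHO regulon relative to all genes was lower at low than at high phosphate by -1.25 at 8 h, but the array designs differ in the same way and growth was not used here, so this could not be decided.

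At high phosphate, ribosomal proteins and glycolysis had the highest mean ranks of the lists, 86.0 and 81.3, with reference genes at 70.9, and the abundance of transcripts was not measured here. A ratio that depends on spot brightness is consistent with this. The mean ratio of a gene at high phosphate fell with its share of blank spots on the low phosphate arrays, with a Spearman rho of -0.341 across 4793 genes. It is not particular to high phosphate, since low phosphate ratios against blanks on the high phosphate arrays gave -0.246 across 5181 genes. The higher ratios of ribosomal proteins at low phosphate may therefore hold a part of it too. Ribosomal protein and glycolysis genes lay above the other reference genes by at least 0.163 on each of the 5 arrays, which leaves open whether they rose beyond spots of similar brightness.

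At high phosphate 0 genes passed. Any 5 of the 6 low phosphate arrays still called genes, so 5 arrays do not prevent calls in that table. The spread and the sizes of change differ between the tables, so this does not decide the question for high phosphate. In the simulation 6 of 50 genes changed by 0.5 were recovered there, but also 45 of 50 changed by 2 and 49 of 50 changed by 4. On the real arrays 0 genes passed, ARR2 and ARR3 included, so the simulation does not reproduce this table. It therefore cannot decide the question, and too few arrays for small changes is not excluded. Stray spots may contribute. Of the 43 gene values below -2 with several spots, 37 (86.0%) came from spots more than 1 apart, against 15% at low phosphate. Over all values with several spots the share was 5.59% at high and 0.93% at low phosphate. Leaving out 1 of the 8 h arrays gave at least 1255 genes, where the spread came from the 4 h pair alone, and leaving out 1 of the 4 h arrays gave 0, so the count followed which pair set the spread.

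The count of 1156 genes between the conditions was set against other splits of the arrays within each time, with as many arrays per side and the same fit. Of 100 splits drawn from 108, 1 called as many genes, the real one itself. The other splits called a median of 0 genes, 79 of them called 0, and the highest called 784. That split moved 4 of the 6 low phosphate arrays to the other side. The splits redraw the arrays within each time as if they were independent. Replicate numbers paired the low phosphate arrays weakly across times, and the labels leave shared cultures possible. A chance division of the arrays is therefore not excluded, and the real split divides phosphate and array design alike. Splits of the 11 arrays into 6 and 5 that ignore time were also fitted, with time as a term and 1 shared difference, where 2 of 100 drawn from 462 called as many as the 396 of the real one. Many of these leave a time on 1 side and carry little information, so nothing is drawn from them. The highest of them, 736, set all 4 h and all 10 h arrays on opposite sides and divided 8 h by phosphate and array design as the real split does.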

How the results depend on the processing

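Values from spots that agree, ranked lists, low minus high phosphate at single times or without 8 h, and the low phosphate mean without 8 h were chosen after the results were seen, as were lists at single times. Leaving out 8 h turned the low phosphate mean of the PHO regulon (0.464), ribosome biogenesis (0.0466), amino acid biosynthesis (0.435) and purine synthesis (0.0466), and of PHO84 (0.25), PHO5 (0.32), SPL2 (0.039), PHO81 (0.0028), VTC3 (0.31) and PHM6 (0.22). For low minus high phosphate the sign turned at 4 h only for TDH1 (0.32), PHO84 (0.58) and PHO5 (1.56), at 10 h only for AIM17 (0.17), MSC1 (0.037) and CTT1 (0.10), and without 8 h for PHO5 (0.22). Other counts moved more than 1.5-fold. The cause of these changes was not tested. Array weights gave 362 genes at low phosphate 4 h. Without 8 h the low phosphate mean had 1148. Spots that agree left 2811 of 5185 genes to test at low phosphate and 1990 of 4841 for low minus high phosphate, so fewer calls follow in part from fewer genes. They gave 1544 at low phosphate 8 h, 1276 for the mean, 1151 for 10 h minus 4 h, 1892 for any time and 651 for low minus high phosphate. At high phosphate, with 1935 of 4816 genes, they gave 336, 430 and 90 at 4, 8 and 10 h, 727 for the mean, 4 for 10 h minus 4 h and 2 for any time, where 0 had passed. The 2-fold rule gave 60, 335 and 70 at 4, 8 and 10 h of low phosphate, 4 for the mean and 164 for 10 h minus 4 h, 34, 31 and 213 at the times of high phosphate, 1 and 25 for its mean and time contrast, and 2 for low minus high phosphate. Low minus high phosphate gave 434 at 4 h only and 207 at 10 h only. With an estimated correlation 0 lists passed in each of the 4 list comparisons, and fry passed 2 for low phosphate 10 h minus 4 h and 11 for the high phosphate mean.

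Leaving out 1 array gave 1090 to 1699 genes at low phosphate 4 h, 1380 to 3048 at 8 h, 609 to 2326 at 10 h, 1407 to 2329 for the mean, 980 to 2076 for 10 h minus 4 h and 2142 to 3473 for any time. By ratio to the full fit, only the low phosphate counts at 8 h, at 10 h and of 10 h minus 4 h moved more than 1.5-fold. At 8 h this happened without either 8 h array, and for the others without either 10 h array. At high phosphate the ranges were 0 to 1 at 4 h, 0 to 564 at 8 h (502 and 564 without the first and second 8 h array), 0 to 1 at 10 h, 0 to 1260 for the mean (1260 and 1255 without those, with spread from the 4 h pair alone), 0 to 0 for 10 h minus 4 h and 0 to 75 for any time. Low minus high phosphate ran from 591 to 1701, with 591 and 681 without the first and second low 8 h array, 680 and 679 without those of 10 h and 758 without the first high 4 h array. Lists ran from 14 to 16 for the low phosphate mean, 7 to 12 for 10 h minus 4 h, 16 to 21 for the high phosphate mean, 3 to 5 for its 10 h minus 4 h (5 without the second 8 h array) and 0 to 14 between conditions, with 0 without any 10 h array, where fewer arrangements exist. The comparisons of high phosphate that use 10 h could not be fitted without its only array. The replicate block changed the calls for which its value is printed beside the result. It also ended the calls of phosphate transporters (0.0752) and ergosterol synthesis (0.0698) for the high phosphate mean, where replicate numbers do not pair the arrays. Calls of single genes were followed over all alternatives only for the genes named here, not for all genes called. Of 2144 values of named genes that passed, 2066 kept their call, 65 lost it and 13 turned sign. Of 965 values of lists that passed, the numbers were 754, 207 and 4. Many named genes were chosen for a large change or an extreme moderated t in the same data. The share of gene calls kept therefore does not describe all genes called. Intensities were not used here, so the dependence on signal could not be tested directly.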

Other observations

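The neighbour and relative of FRM2, HBN1, which encodes a similar nitroreductase-like protein, was looked at after its values were seen. At low phosphate it rose between 4 h and 10 h by 1.46 (SE 0.17, adjusted p = 4.91e-06), while ARR2 fell by 1.81 over the same interval. At high phosphate it stood at 1.98 (SE 0.43, adjusted p = 0.888) for 10 h minus 4 h and did not pass, from 1 array at each time, so whether the rise is particular to low phosphate was not shown. At 4, 8 and 10 h HBN1 stood at -0.46, 0.47 and 1.00 at low phosphate and at -1.54, -0.01 and 0.44 at high phosphate. The -1.54 came from 1 array and weighs on the difference between conditions. Averaged over the times HBN1 was higher at low than at high phosphate by 0.71 (SE 0.15, adjusted p = 0.0143). That call ended without the first low phosphate 8 h array (0.0502), at 8 h only (0.48, 0.141) and at 10 h only (0.56, 0.266), in a range over its alternatives from 0.000267 to 0.266.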
